A study of Mus musculus with 22 samples.

How the data were processed

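Tumour-infiltrating cells of C57BL/6 mice were enriched for CD45, an antigen of blood cells, and live CD3 and CD8 positive cells that bound or did not bind the mLama4 tetramer were sorted, per the labels' protocols. Libraries were made for strand-specific sequencing of 3' ends, with a sample barcode in the oligo-dT primer, pooling after first-strand synthesis and PCR, per the labels' protocols. No molecular identifiers are mentioned there, so reads are not independent molecules. TopHat and the genome build mm9 are named in the submitters' processing notes; the TopHat version, the counting tool and the annotation release are not given in the sources used here.

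The deposited values are on a log2 scale, 1 value per gene and library for 39176 genes and 22 libraries. The values themselves show how they were made: apart from ties, the high ranks hold nearly the same values in every library, zeros stay at 0, and the smallest value above 0 in the table equals the mean over 22 libraries of a single log2(count + 1) of 1 read, so the authors took log2(count + 1) and then quantile-normalised over the 22 libraries. Quantile normalisation gives all libraries nearly one distribution, so a change in total RNA cannot be seen, and shallow libraries reach the same high values as deep ones while more of their low genes lie at 0. A fold is therefore a fold on this scale. The smallest value above 0 ran from 0.0455 to 3.91 over the libraries, so a change of a low gene to 0 can appear too large in a shallow library. No read totals follow from such values. Ordering the distinct values of a library, each step standing for at least 1 read, gives a lower bound of the reads per gene, and the bound at the gene ranked 8000 was used to compare depth. Between 0.14% and 6.72% of the values of tested genes were 0 per library.

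Gene identifiers are used as the table gives them. Symbols were taken from a table of gene names by the identifier without its version, which matched 37607 of 39176 identifiers and 9927 of the 10000 tested. The build of that reference differs from mm9, so no coordinates are given. Reads of near-identical genes, such as the haemoglobin, H2 and Ly49 (Klra) genes and ribosomal protein genes with their pseudogenes, can be split between copies, and their values are uncertain to that degree.

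Groups were taken from the sample titles. The 10000 genes with the highest mean over all libraries were tested with limma (version 3.58.1, in R 4.3.3), in one fit of the 8 groups over 22 libraries without covariates, with a mean-dependent trend in the spread and Benjamini-Hochberg adjustment at a threshold of 0.05. A gene at 0 in every library of a group has no fold, and such a gene is given as listed at 0. The comparisons were each treatment with the control antibody in each gate, the treatments with each other in tetramer-positive cells, the gates averaged over treatments, and the interaction of gate and treatment. The labels do not say that replicates come from separate animals, and p-values then measure only the spread between these samples, which may be technical. The most alike pair of libraries had a correlation of 0.881 and none was a duplicate of another.

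Lists of 31 pathways, cell types and quality markers were written from general knowledge, and 29 had at least 5 tested members. Neutrophil and endothelial markers, with 3 and 2 tested members, were not tested as lists. Lists were tested with camera from limma with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison; camera with a correlation estimated from the data and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, stand beside it. The range beside a list gives its lowest and highest median over all alternative settings. The setting with the sarcoma and dendritic list levels as covariates removes the mean effect of those lists by construction. List levels per library, the mean over members, were compared with exact permutation tests. Named genes followed a fixed rule: the passing genes with the largest change per direction that did not overlap between the groups (10 per direction for comparisons with the control antibody in tetramer-positive cells and for the gates, where the sign had to hold in all 4 treatments, and 5 elsewhere), or the 3 with the smallest p per direction where none passed, a panel of 31 genes, of which 30 were tested, and up to 4 members of each called list, those with the smallest p among the members that moved the way of the list. Gene models without a proper name were counted and not named. Results of some genes that the rule names are not reported here. The gene tests, the lists, most of the rule for names and most alternatives were chosen before the data were examined. The narrowing to members that moved the way of the list, the list tests of direct comparisons, the gates within treatments and the tests of marker shares and of the gate signature were chosen after.

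The procedure was tested on simulated data for the combination against the control antibody in tetramer-positive cells, with 10000 genes. The changed genes were drawn from those with means above the median, so recovery among low genes is not known. It recovered 100% of 50 genes lowered by 3 on the log2 scale, 78% of 50 lowered by 2, 2% of 50 lowered by 1 and 8% of 50 raised by 1, and called 0 of 9774 unchanged genes. The glycolysis list raised by 1 was found (adjusted p = 2.94e-26), but 4 of 28 other lists were called as well, so camera with the preset correlation is lenient here.

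The alternatives were no filter, a stricter filter of 6000 genes, a pseudocount of 16, a trimmed mean shift per library, no trend, library quality weights, a fit of only the groups compared, a block for replicate number, each library left out in turn, and the other list tests. Leaving out 3 libraries with markers of the other gate, and adding 2 marker levels as covariates, were chosen after seeing the data. A table of primer barcodes without replicate numbers was not used.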

Results

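RNA was measured in CD8 T cells sorted from tumours of C57BL/6 mice that had received a control antibody, an antibody against PD-1 (aPD1), an antibody against CTLA-4 (aCTLA4) or both antibodies (the combination). PD-1 and CTLA-4 are inhibitory receptors of T cells. In each treatment, cells that bound a tetramer carrying a peptide of mutant laminin alpha 4 (mLama4, an antigen of the tumour) and cells that did not bind it were sequenced apart, which makes 8 groups. The 22 libraries comprise 3 per group, except for 2 in tetramer-positive cells with aPD1 and 2 in tetramer-negative cells with the combination. The libraries hold 3' end reads, and the values are on a log2 scale after quantile normalisation. Library depth was known only as a lower bound: the gene ranked 8000 had at least 29 reads in the shallowest library (combination, tetramer-negative replicate 2). That library had 10388 genes above 0, and the deepest, aPD1 tetramer-positive replicate 1, had 14080. Lower bounds in the combination were 54, 35 and 44 in tetramer-positive and 47 and 29 in tetramer-negative libraries, against 83, 43 and 154 and 76, 75 and 78 with the control antibody.

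The first question was what aPD1 changed in T cells that recognise the mutant antigen. In the 2 tetramer-positive libraries with aPD1, genes that T cell receptor signals induce within minutes to hours were lower than in the 3 libraries with the control antibody (median log2 difference -0.49, 31 of 34 members lower, adjusted p = 2.75e-08, and adjusted p = 0.273 with an estimated correlation, range -0.79 to -0.16). The median was -0.79 without aPD1 replicate 1 and -0.16 without replicate 2, where a single library is left in the group. Within this list the nuclear receptor Nr4a1 differed by -1.25 ± 0.35 (log2 difference ± SE), the immediate early gene Ier2 by -1.18 ± 0.41 and the mRNA decay factor Zfp36 by -1.20 ± 0.42. 1 member passed adjusted over the list alone and 0 over all genes. The chemokine gene Xcl1, whose product attracts cross-presenting dendritic cells, was at 11.06 ± 1.26 (SD, n = 2) against 12.89 ± 0.02 (SD, n = 3), but its difference of -1.84 ± 0.42 did not pass over all genes (adjusted p = 0.726 by limma). Chemokines and cytokines were lower as a list (median log2 difference -0.31, 16 of 22 members lower, adjusted p = 0.00367, and adjusted p = 0.273 with an estimated correlation, range -0.41 to -0.17). Their median was -0.20 without the control antibody replicate 1. Among them Ccl5 was at -0.88 and Ccl4 at -0.89, and 3 members passed adjusted over the list alone.

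Other gene groups also differed with aPD1 in tetramer-positive cells. Cytotoxic effector genes had a median log2 difference of -0.41 (adjusted p = 0.00244, or 0.273 with an estimated correlation, range -0.51 to -0.19), with the interferon gamma gene Ifng at -1.01 ± 0.36, the cathepsin Ctsw at -0.999 and the granule proteoglycan Srgn at -0.90. Inhibitory receptors and exhaustion genes had a median of -0.21 (adjusted p = 0.00625, or 0.273 with an estimated correlation, range -0.29 to -0.0457), and Cd160, a receptor of exhausted T cells, was the 1 member that passed adjusted over the list alone (-1.26 ± 0.33). Costimulatory receptors had a median of -0.24 (adjusted p = 0.0285, or 0.273 with an estimated correlation, range -0.32 to -0.12). Genes of CD8 T cell identity stood at -0.43 (adjusted p = 7.22e-04, or 0.273 with an estimated correlation, range -0.54 to -0.24). Ribosomal protein genes stood at -0.43 (adjusted p = 1.63e-06, or 0.273 with an estimated correlation, range -0.55 to -0.39). Oxidative phosphorylation genes stood at -0.32 (adjusted p = 1.39e-05, or 0.492 with an estimated correlation, range -0.43 to -0.23). Glycolysis genes stood at -0.28 (adjusted p = 0.0339, or 0.393 with an estimated correlation, range -0.54 to -0.11). Genes of amino acid transport and ATF4 targets stood at -0.23 (adjusted p = 0.0285, or 0.273 with an estimated correlation, range -0.37 to -0.12). Genes of the cell cycle were higher: S phase by 0.27 (adjusted p = 0.0132, or 0.635 with an estimated correlation, range -0.0938 to 0.60), with Clspn at 1.20. G2 and mitosis stood at 0.35 (adjusted p = 8.18e-04, or 0.686 with an estimated correlation, range -0.15 to 0.90), with Cenpf at 1.03. Transcripts of other cells moved too, with macrophage and monocyte markers at -1.18 (adjusted p = 1.04e-06, or 0.273 with an estimated correlation, range -2.79 to 0.48). Sarcoma and fibroblast markers stood at -1.64 (adjusted p = 1.22e-04, or 0.32 with an estimated correlation, range -4.82 to 0.77). The 2 aPD1 libraries differed from each other in these markers: sarcoma and fibroblast genes averaged 8.26 and 2.95, macrophage markers 8.68 and 4.70, and dendritic cell markers 6.99 and 2.99 in replicates 1 and 2.

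In this comparison 0 of 10000 genes passed by limma (543 at an unadjusted p under 0.05), and 14 of 29 lists did, of which 0 held with an estimated correlation. The 3 genes per direction with the smallest p, none of which passed, were Ppp2r2d (1.497), Ppil2 (1.70) and Ccdc171 (4.69) on the higher side, and Xcl1, Gnpda1 (-5.73) and Ifitm1 (-1.74) on the lower side. Of the 30 panel genes, which cover checkpoint receptors, effector and memory genes, 0 passed over all genes and 0 adjusted over the panel alone. Without a filter the count was 4 genes, without the control antibody replicate 3 it was 1, without aPD1 tetramer-positive replicate 1 it was 9, and without aPD1 replicate 2 the directions of the cell cycle, macrophage and sarcoma lists turned (medians of -0.09 for S phase, -0.15 for G2 and mitosis, 0.48 for macrophage and 0.77 for sarcoma genes). Without either aPD1 library 1 library stands for the group and is assumed to vary like the others.

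With aCTLA4, tetramer-positive cells had more RNA of genes that act in cell division. All 62 measured genes of G2 and mitosis were higher than with the control antibody (median log2 difference 0.90, 62 of 62 members higher, adjusted p = 1.57e-21, and adjusted p = 0.136 with an estimated correlation, range 0.33 to 1.09), and 16 passed adjusted over the list alone against 0 over all genes. Among them were Top2a, which untangles chromosomes, at 0.95 ± 0.30, the mitotic kinase Aurkb at 1.66 ± 0.52, the chromosomal passenger Incenp at 0.93 ± 0.28 and the kinetochore protein Cenpf at 1.15 ± 0.36 (log2 difference ± SE, n = 3 and n = 3). Genes of S phase were higher as well (median log2 difference 0.67, 45 of 47 members higher, adjusted p = 1.34e-11, and adjusted p = 0.134 with an estimated correlation, range 0.28 to 0.72), with the replication factor Rfc4 at 1.26 and the DNA methylation factor Uhrf1 at 1.20. The proliferation marker Mki67 differed by 1.70 ± 0.54. Mki67, Top2a and the cytokine gene Tnf (-1.46 ± 0.38) were the 3 panel genes that passed adjusted over the panel alone, and 0 passed over all genes.

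Early response genes were lower with aCTLA4 (median log2 difference -0.45, 30 of 34 members lower, adjusted p = 2.19e-08, and adjusted p = 0.134 with an estimated correlation, range -0.54 to -0.27), with Zfp36 at -1.29, the phosphatase Dusp2 at -0.88 and Jund at -0.74. Chemokines and cytokines were lower (median log2 difference -0.29, 18 of 22 members lower, adjusted p = 8.44e-04, and adjusted p = 0.134 with an estimated correlation, range -0.50 to -0.17). Their median was -0.50 and -0.46 without aCTLA4 replicates 2 and 3 and -0.17 and -0.46 without the control antibody replicates 1 and 3. Xcl1 was at 11.13 ± 0.64 (SD, n = 3) against 12.89 ± 0.02 (SD, n = 3), a difference of -1.76 ± 0.38 that did not pass over all genes (adjusted p = 0.369). Heat shock and dissociation stress genes, a quality list, had a median of -0.47 (adjusted p = 0.00294, or 0.44 with an estimated correlation, range -0.65 to -0.19). Hspa1a was at -1.17. Ribosomal protein genes stood at -0.30 (adjusted p = 0.001, or 0.481 with an estimated correlation, range -0.38 to -0.21). CD8 T cell identity genes stood at -0.32 (adjusted p = 0.0104, or 0.44 with an estimated correlation, range -0.46 to -0.16). Markers of other cells stood apart in these libraries. Macrophage and monocyte markers had a median of -1.54 (adjusted p = 6.46e-10, or 0.185 with an estimated correlation, range -2.06 to -0.35), with the signalling adaptor Tyrobp at -3.17. Dendritic cell markers had a median of -1.66 (adjusted p = 3.36e-04, or 0.273 with an estimated correlation, range -2.25 to -0.22), and the growth factor receptor Flt3, at 6.77, 3.12 and 6.10 with the control antibody, was listed at 0 in all 3 aCTLA4 libraries. Natural killer cell markers, a list that shares Xcl1 and Tyrobp with other lists, were at -0.99 (adjusted p = 0.00153, or 0.134 with an estimated correlation, range -1.61 to -0.58). Gamma delta T cell markers stood at -0.89 (adjusted p = 0.0371, or 0.44 with an estimated correlation, range -1.60 to -0.18). Sarcoma and fibroblast markers stood at -1.49 (adjusted p = 0.00143, or 0.44 with an estimated correlation, range -1.76 to 1.57e-04). Red blood cell genes were higher, at 3.56 (adjusted p = 7.83e-07, or 0.164 with an estimated correlation, range 2.01 to 4.26), with the haemoglobin gene Hba-a2 at 3.78, and all 6 members passed adjusted over the list alone.

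By limma 0 of 10000 genes passed for aCTLA4 in tetramer-positive cells (646 at an unadjusted p under 0.05), and 13 lists did, of which 0 held with an estimated correlation. The genes with the smallest p, all short of the threshold, were the recombination gene Rad54l (1.57), Traip (2.87) and Cep128 (1.46) on the higher side and Xcl1, Plbd1 (-4.94) and Cadm1 (-4.69) on the lower. Without the control antibody replicate 1 the lists numbered 8, and without the control antibody replicate 3 there was 1 gene. In a fit of these 2 groups alone 4 genes passed.

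The combination lowered 6 genes in tetramer-positive cells and raised 0. Pdcd1 (ENSMUSG00000026285.6), the gene of PD-1 itself, fell from 10.96 ± 0.20 (SD, n = 3) to 9.29 ± 0.28 (SD, n = 3), or 3.17-fold (log2 difference -1.66 ± 0.30, adjusted p = 0.0354 by limma). Dapl1 (ENSMUSG00000026989.5) fell from 10.06 ± 0.29 (SD, n = 3) to 7.52 ± 1.03 (SD, n = 3) (log2 difference -2.54 ± 0.47, adjusted p = 0.0354), and Tmem106b (ENSMUSG00000029571.8), a lysosomal membrane protein, by 3.42-fold (log2 difference -1.77 ± 0.35, adjusted p = 0.0431). The other 3 genes are typical of other cells. Palld (ENSMUSG00000058056.9), an actin-associated protein of fibroblasts and muscle, was at 7.40, 6.60 and 6.49 with the control antibody and listed at 0 in all 3 combination libraries (adjusted p = 0.0193). Fcgr2b (ENSMUSG00000026656.9), an inhibitory Fc receptor, was at 7.95, 7.39 and 6.67 against 0, 0 and 3.32 (adjusted p = 0.0431). Il12b (ENSMUSG00000004296.8), a subunit of interleukin 12 made by dendritic cells and macrophages, was at 8.93, 6.72 and 6.78 against 0, 3.55 and 3.68 (adjusted p = 0.0475). Over the alternative settings Pdcd1 passed in 7 of 16 (log2 difference from -1.80 to -1.42, adjusted p from 0.0134 to 0.955), Dapl1 in 8 of 16 (log2 difference from -3.32 to -2.19, adjusted p from 0.00455 to 0.277) and Tmem106b in 5 of 16 (log2 difference from -2.18 to -1.56, adjusted p from 0.0297 to 0.696). Palld passed in 10 of 15 (adjusted p from 0.00826 to 0.955), Fcgr2b in 2 of 15 (adjusted p from 0.0365 to 0.955) and Il12b in 1 of 15 (adjusted p from 0.037 to 0.955).

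The cytotoxic effector list did not pass with the combination (median log2 difference 0.20, adjusted p = 0.0565). The granzyme A gene Gzma was at 11.45 ± 0.32 (SD, n = 3) against 9.83 ± 0.26 (SD, n = 3) with the control antibody, a difference of 1.62 ± 0.37 that did not pass over all genes (adjusted p = 0.0807), and Ifng was at 13.53 ± 0.60 (SD, n = 3) against 12.43 ± 0.16 (SD, n = 3) (1.10 ± 0.32, adjusted p = 0.197). Both passed adjusted over the panel alone, as did Pdcd1, the effector cell receptor Klrg1 (3.71 ± 1.21) and the CD8 beta chain Cd8b1 (-0.68 ± 0.23), so 5 of 30 panel genes passed on that basis and 1 over all genes. The cell cycle lists were higher, S phase by 0.39 (adjusted p = 3.66e-05, or 0.438 with an estimated correlation, range 0.20 to 0.54) with 3 members passing adjusted over the list alone, and G2 and mitosis by 0.59 (adjusted p = 7.3e-09, or 0.438 with an estimated correlation, range 0.33 to 0.79). Among them the S phase gene Uhrf1 was at 1.79 and the mitotic checkpoint gene Bub1b at 1.12. Chemokines and cytokines were at -0.36 (adjusted p = 0.0234, or 0.438 with an estimated correlation, range -0.50 to -0.18), with Csf1 at -1.28 and Xcl1 at -1.31, and 5 members passed lower and 1 higher adjusted over the list alone. Oxidative phosphorylation genes were at -0.34 (adjusted p = 8.41e-05, or 0.483 with an estimated correlation, range -0.60 to -0.12). Ribosomal protein genes stood at -0.42 (adjusted p = 6.31e-06, or 0.438 with an estimated correlation, range -0.65 to -0.30). Heat shock genes stood at -0.34 (adjusted p = 8.29e-04, or 0.438 with an estimated correlation, range -0.60 to 0.18), with Dnajb1 at -1.91.

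Transcripts of tumour and stroma were the group that differed most in size with the combination. Sarcoma and fibroblast genes were lower in tetramer-positive cells (median log2 difference -4.65, 20 of 21 members lower, adjusted p = 1.12e-16, and adjusted p = 0.132 with an estimated correlation, range -4.81 to 0.31), with the collagen Col1a1 at -5.06 ± 1.18 and the matrix protein Sparc at -5.97 ± 1.34. The collagen Col4a1, at 7.32, 7.79 and 6.46 with the control antibody, was listed at 0 in all 3 combination libraries. 15 of 21 passed adjusted over the list alone and 0 over all genes, and fry gave an adjusted p of 0.0355. Per library the list averaged 3.37 ± 0.57 (SD, n = 3) against 7.40 ± 0.48 (SD, n = 3). Macrophage and monocyte markers were lower (median log2 difference -1.84, 28 of 29 members lower, adjusted p = 3.39e-16, and adjusted p = 0.181 with an estimated correlation, range -2.47 to -0.61), with the complement gene C1qc at -6.83 and the arginase Arg1 at -6.97, and 16 passed adjusted over the list alone. Dendritic cell markers were at -1.60 (adjusted p = 0.0155, or 0.445 with an estimated correlation, range -1.85 to 0.27). Gamma delta T cell markers stood at -1.65 (adjusted p = 0.0473, or 0.445 with an estimated correlation, range -2.80 to -5.68e-05). Red blood cell genes stood at 2.37 (adjusted p = 0.00522, or 0.445 with an estimated correlation, range -3.67 to 3.53). Of the 29 lists 11 passed, 0 with an estimated correlation and 1 by fry, and 979 genes had an unadjusted p under 0.05. The count of 6 genes was 0 without the control antibody replicate 1 or replicate 2, 3 without its replicate 3 or without combination replicate 1, 2 without combination replicate 3, and 1 without 3 libraries whose dendritic markers lay with the other gate (control antibody tetramer-positive 1, aPD1 tetramer-positive 1 and control antibody tetramer-negative 3, chosen after seeing the data). It was 13 with a pseudocount of 16, 11 in a fit of the 2 groups alone, 3 under the stricter filter, 1 without a trend in the spread and 0 with marker levels as covariates, and of 8 genes that passed without a filter only 1 was among the 6.

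**Figure D1:**
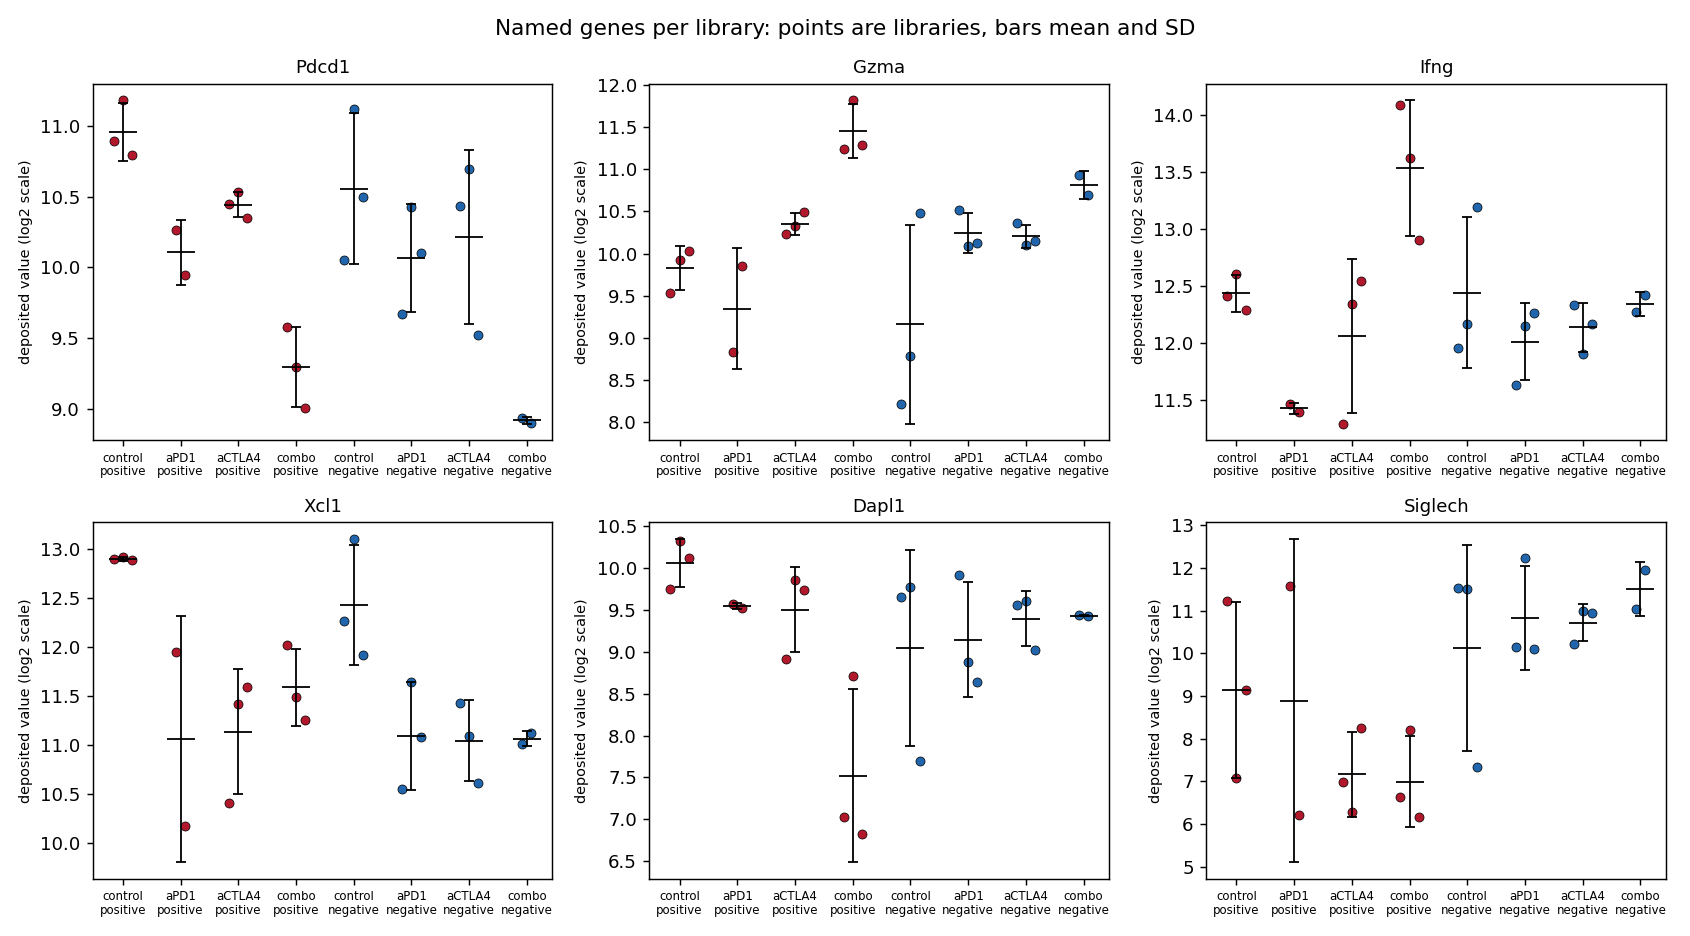
Deposited log2 values of Pdcd1, Gzma, Ifng, Xcl1, Dapl1 and the plasmacytoid dendritic cell gene Siglech in each of the 22 libraries (y axis), by treatment and gate (x axis, red for tetramer-positive and blue for tetramer-negative), with bars for the mean and SD of each group. Pdcd1 averaged 9.29 and 8.92 in the combination groups against 10.96 and 10.56 with the control antibody.

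Tetramer-negative cells, which hold the other CD8 T cells of the tumour, were compared in the same way. With the combination, Pdcd1 fell here too, from 10.56 ± 0.53 (SD, n = 3) to 8.92 ± 0.02 (SD, n = 2), or 3.11-fold (log2 difference -1.64 ± 0.34, adjusted p = 0.0319 by limma). Gzma was at 10.81 ± 0.17 (SD, n = 2) against 9.16 ± 1.18 (SD, n = 3) (1.65 ± 0.41, adjusted p = 0.104), and Pdcd1 and Gzma were the 2 panel genes that passed adjusted over the panel alone. Over the alternative settings Pdcd1 passed here in 3 of 15 (log2 difference from -1.89 to -1.27, adjusted p from 0.0336 to 0.832). Among the genes with the largest falls, decorin (Dcn), a matrix protein of fibroblasts, was at 9.31, 9.22 and 8.25 with the control antibody against 2.84 and 0 (adjusted p = 0.0138). The matrix signalling gene Ccn1 (at 8.47, 7.52 and 6.17 with the control antibody, adjusted p = 0.0264), Kcnf1 (6.59, 7.22 and 7.02), Gpr146 (8.02, 7.33 and 4.98) and Wdr53 (7.05, 5.83 and 7.07) were listed at 0 in both combination libraries. Over the alternative settings Dcn passed in 7, Ccn1 in 8, Kcnf1 in 5, Gpr146 in 7 and Wdr53 in 3 of 14.

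Genes induced by type I interferon were higher in tetramer-negative cells with the combination (median log2 difference 0.60, 34 of 38 members higher, adjusted p = 8.21e-06, and adjusted p = 0.555 with an estimated correlation, range 0.22 to 0.99). Their median was 0.99 and 0.35 without combination replicates 1 and 2. The antiviral genes among them include Mx1 at 1.88 ± 0.63 and Ifit1 at 1.54 ± 0.63, and 0 passed adjusted over the list alone. The interferon gamma list was at 0.15 (adjusted p = 0.0372, or 0.555 with an estimated correlation, range -0.41 to 0.27), with the PD-L1 gene Cd274 at 1.29. G2 and mitosis stood at 0.35 (adjusted p = 0.00208, or 0.604 with an estimated correlation, range 0.13 to 1.35). Chemokines and cytokines were at -0.38 (adjusted p = 0.042, or 0.555 with an estimated correlation, range -0.73 to -0.0985). Oxidative phosphorylation stood at -0.40 (adjusted p = 1.11e-04, or 0.555 with an estimated correlation, range -0.54 to -0.20). Heat shock stood at -0.63 (adjusted p = 0.00285, or 0.555 with an estimated correlation, range -1.22 to -0.0384). Ribosomal proteins stood at -0.44 (adjusted p = 7.15e-04, or 0.555 with an estimated correlation, range -0.69 to -0.30). Sarcoma and fibroblast genes were lower (median log2 difference -4.85, 20 of 21 members lower, adjusted p = 8.72e-15, and adjusted p = 0.196 with an estimated correlation, range -5.48 to 0.00445), 14 passing adjusted over the list alone and 2 over all genes. Macrophage markers were at -0.55 (adjusted p = 0.0108, or 0.595 with an estimated correlation, range -1.17 to 0.24). Dendritic cell markers stood at 0.996 (adjusted p = 0.042, or 0.555 with an estimated correlation, range -0.0233 to 1.69). Red blood cell genes stood at 2.80 (adjusted p = 0.00305, or 0.555 with an estimated correlation, range -5.73 to 5.96). By limma 21 genes passed, all lower (1042 at an unadjusted p under 0.05), and 11 lists, of which 0 held with an estimated correlation and 1 by fry. The count of 21 genes was 0 without the control antibody replicate 1 or replicate 2, 200 without combination replicate 1 and 46 without combination replicate 2, where 1 library stands for the group and is assumed to vary like the others. Without combination replicate 1 the lists numbered 5 and the red blood cell median turned (-0.42), without replicate 2 the macrophage median did (0.13), and without the control antibody replicate 3 the dendritic median did (-0.02). The gene count was 0 with library weights, with a pseudocount of 16, with marker levels as covariates and in a fit of the 2 groups alone, and 2 under the stricter filter.

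With aPD1, tetramer-negative cells had lower early response genes (median log2 difference -0.48, 32 of 34 members lower, adjusted p = 2.82e-08, and adjusted p = 0.121 with an estimated correlation, range -0.72 to -0.33). Their median was -0.72 without the control antibody replicate 3. Among them the transcription factor Egr2 was at -1.47 ± 0.57 and Zfp36 at -1.20 ± 0.38. Type I interferon genes were at 0.30 (adjusted p = 0.0105, or 0.685 with an estimated correlation, range 0.11 to 0.50). Oxidative phosphorylation stood at -0.34 (adjusted p = 7.83e-06, or 0.684 with an estimated correlation, range -0.46 to -0.20). Amino acid transport and ATF4 targets stood at -0.35 (adjusted p = 3.45e-04, or 0.121 with an estimated correlation, range -0.39 to -0.26). Ribosomal proteins stood at -0.33 (adjusted p = 6.77e-04, or 0.684 with an estimated correlation, range -0.41 to -0.17). Sarcoma and fibroblast markers were at -3.17 (adjusted p = 5.38e-09, or 0.194 with an estimated correlation, range -3.92 to 0.0388). B cell markers stood at 2.48 (adjusted p = 0.0105, or 0.121 with an estimated correlation, range -0.75 to 3.11). Genes of red blood cells stood at 3.22 (adjusted p = 7.96e-05, or 0.339 with an estimated correlation, range -1.30 to 4.66). Of all genes 0 passed by limma (618 at an unadjusted p under 0.05), 0 panel genes passed on either basis, and 0 of the 8 lists called held with an estimated correlation. The genes with the smallest p, none passing, were Cdr2 (4.94), Rpl6 (1.48), Mink1 (1.58), Trmt61b (-5.64), Lasp1 (-1.07) and Xcl1 (-1.33). Without the control antibody replicate 3 the count was 2, and 3 without the 3 libraries named above. It was 1 without a trend in the spread and 2 without a filter.

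With aCTLA4, tetramer-negative cells had higher cell cycle lists, S phase at 0.27 (adjusted p = 0.0121, or 0.704 with an estimated correlation, range 0.0716 to 0.50), with Hells at 0.99 ± 0.36. G2 and mitosis stood at 0.35 (adjusted p = 8.59e-04, or 0.704 with an estimated correlation, range 0.12 to 0.75), with Sgo2a at 1.56 ± 0.53. Early response genes were at -0.23 (adjusted p = 0.00662, or 0.704 with an estimated correlation, range -0.41 to -0.12). Oxidative phosphorylation stood at -0.16 (adjusted p = 0.0203, or 0.704 with an estimated correlation, range -0.35 to 0.0484). Amino acid transport and ATF4 targets stood at -0.36 (adjusted p = 0.00662, or 0.309 with an estimated correlation, range -0.42 to -0.24). B cell markers were at 2.73 (adjusted p = 0.00662, or 0.215 with an estimated correlation, range 0.41 to 3.08). Genes of red blood cells stood at 3.43 (adjusted p = 2.68e-06, or 0.309 with an estimated correlation, range 2.45 to 3.98). Of all genes 0 passed by limma (439 at an unadjusted p under 0.05), 0 panel genes passed on either basis, and 0 of the 7 lists called held with an estimated correlation. The genes with the smallest p, none passing, were Cdr2 (4.55), the platelet genes Alox12 and Gp1bb, both listed at 0 in 2 of 3 control libraries, Xcl1 (-1.38), Zfp513 (-2.75) and Crabp2 (-4.19). The count was 2 without the control antibody replicate 3, 5 without the 3 libraries named above, 5 in a fit of the 2 groups alone and 1 without a trend in the spread. Without aCTLA4 tetramer-negative replicate 3 the median of oxidative phosphorylation was 0.05.

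Treatments were then compared with each other in tetramer-positive cells. Against aPD1, the combination had higher Ifng (13.53 ± 0.60 (SD, n = 3) against 11.42 ± 0.05 (SD, n = 2), log2 difference 2.11 ± 0.36, adjusted p = 0.0294), higher Gzma (4.29-fold, log2 difference 2.10 ± 0.41, adjusted p = 0.0391) and higher Ccl3, a chemokine of activated T cells (3.52-fold, log2 difference 1.82 ± 0.34, adjusted p = 0.0338). Pdcd4, an inhibitor of translation, was 4.02-fold lower (log2 difference -2.01 ± 0.38, adjusted p = 0.0338). Over the alternative settings Ifng passed in 6 of 15 (log2 difference from 1.83 to 2.43, adjusted p from 0.00646 to 0.264) and Gzma in 4 of 15 (log2 difference from 1.59 to 2.61, adjusted p from 0.0224 to 1). Shtn1, listed at 0 in 2 of 3 combination libraries, and Il12b, at 0 in 1, were lower as well (adjusted p = 0.0391 and 0.0338). Ccl3 and Pdcd4 passed in 6 and 6 of 15 settings, Shtn1 and Il12b in 4 and 6 of 14. Cytotoxic effector genes were higher as a list (median log2 difference 0.51, 19 of 25 members higher, adjusted p = 2.12e-07, and adjusted p = 0.109 with an estimated correlation, range 0.31 to 0.65). Their median was 0.31 without aPD1 replicate 1 and 0.33 without combination replicate 1. With all libraries 3 members passed adjusted over the list alone and 2 over all genes. Lists for direct comparisons were tested only after seeing the data. Early response genes were at 0.33 (adjusted p = 5.47e-04, or 0.456 with an estimated correlation, range 0.0517 to 0.58). Amino acid transport and ATF4 targets stood at 0.49 (adjusted p = 5.19e-05, or 0.0943 with an estimated correlation, range 0.32 to 0.76). Costimulatory receptors stood at 0.25 (adjusted p = 0.036, or 0.456 with an estimated correlation, range 0.16 to 0.32). Heat shock stood at -0.53 (adjusted p = 2.99e-04, or 0.456 with an estimated correlation, range -0.90 to -0.28). G2 and mitosis stood at 0.18 (adjusted p = 0.0174, or 0.715 with an estimated correlation, range -0.30 to 0.66). Sarcoma and fibroblast markers moved with them, at -2.25 (adjusted p = 4.89e-07, or 0.456 with an estimated correlation, range -5.44 to 0.65), as did macrophage markers at -0.90 (adjusted p = 3.26e-04, or 0.467 with an estimated correlation, range -2.57 to 0.50). Dendritic cell markers stood at -1.27 (adjusted p = 0.0207, or 0.467 with an estimated correlation, range -3.87 to 0.21). Genes of red blood cells stood at 2.68 (adjusted p = 6.87e-04, or 0.467 with an estimated correlation, range -0.27 to 4.89). The 6 genes by limma (487 at an unadjusted p under 0.05) were 1 without aPD1 replicate 1 and 3 without aPD1 replicate 2, where 1 aPD1 library stands for the group. They were 2 without combination replicate 1 and 3 without its replicate 2 or 3. They were 0 without the 3 libraries named above, without a trend in the spread, with marker levels as covariates and in a fit of the 2 groups alone, and of 10 genes that passed without a filter 0 were among them. Without aPD1 replicate 1, the medians of G2 and mitosis (-0.30), macrophage (0.50), dendritic (0.09), sarcoma (0.65) and red blood cell genes (-0.27) turned, and without combination replicate 1 that of G2 and mitosis (-0.02).

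Between the combination and aCTLA4, 0 genes passed by limma (551 at an unadjusted p under 0.05). The smallest p belonged to Ifng (1.47 ± 0.32, adjusted p = 0.423), the interferon-induced Ifit1 (2.30) and Mtmr6 (1.38) on the higher side, and to Tmem106b (-1.63), Wsb2 (-2.54) and Tm4sf1, listed at 0 in all 3 combination libraries, on the lower. Type I interferon genes were higher with the combination, at 0.53 (adjusted p = 3.37e-04, or 0.593 with an estimated correlation, range 0.0269 to 0.87). Cytotoxic effector genes stood at 0.24 (adjusted p = 0.00833, or 0.593 with an estimated correlation, range -0.0752 to 0.44). Early response genes stood at 0.26 (adjusted p = 0.00197, or 0.593 with an estimated correlation, range 0.00439 to 0.32). G2 and mitosis was lower, at -0.31 (adjusted p = 0.0047, or 0.79 with an estimated correlation, range -0.48 to 0.17), as was oxidative phosphorylation at -0.25 (adjusted p = 0.00291, or 0.79 with an estimated correlation, range -0.44 to -0.0983). Macrophage markers stood at -0.65 (adjusted p = 0.00397, or 0.79 with an estimated correlation, range -1.16 to -0.0634). Sarcoma and fibroblast markers stood at -2.71 (adjusted p = 1.48e-10, or 0.303 with an estimated correlation, range -3.22 to 0.18). Amino acid transport and ATF4 targets stood at 0.20 (adjusted p = 0.00828, or 0.303 with an estimated correlation, range 0.0914 to 0.35). Without combination replicate 1 the count was 3 genes and the median of cytotoxic effector genes turned (-0.08). Without a filter 5 genes passed.

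Between aPD1 and aCTLA4, 0 genes passed by limma (416 at an unadjusted p under 0.05). The smallest p belonged to Pdcd4 (1.74 ± 0.38, adjusted p = 0.666), Ppil2 (1.76) and Nrd1 (1.29), which were higher with aPD1, and to the platelet integrin Itga2b, listed at 0 in both aPD1 libraries, Gng11 (-6.02) and Gnpda1 (-5.07). G2 and mitosis was lower with aPD1, at -0.47 (adjusted p = 3.98e-08, or 0.456 with an estimated correlation, range -1.00018 to 0.23), as was S phase at -0.38 (adjusted p = 2.32e-04, or 0.456 with an estimated correlation, range -0.74 to 0.0221). Cytotoxic effector genes stood at -0.27 (adjusted p = 0.00398, or 0.456 with an estimated correlation, range -0.46 to -0.14). Glycolysis stood at -0.38 (adjusted p = 0.0121, or 0.456 with an estimated correlation, range -0.44 to -0.21). Oxidative phosphorylation stood at -0.28 (adjusted p = 0.00142, or 0.627 with an estimated correlation, range -0.41 to -0.15). Type I interferon genes were at 0.57 (adjusted p = 2.38e-04, or 0.456 with an estimated correlation, range 0.0295 to 0.71). Heat shock stood at 0.39 (adjusted p = 0.00471, or 0.478 with an estimated correlation, range 0.23 to 0.88). Dendritic cell markers were at 1.40 (adjusted p = 0.00142, or 0.456 with an estimated correlation, range -0.33 to 3.19). Red blood cell genes stood at -3.86 (adjusted p = 2.48e-07, or 0.456 with an estimated correlation, range -6.18 to -1.12). The count was 7 genes without a filter and 1 gene without aPD1 replicate 2, and without aPD1 replicate 1 the medians of G2 and mitosis (0.02) and dendritic markers (-0.02) turned. Here too 1 aPD1 library is left and stands for the group.

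Tetramer-positive and tetramer-negative cells were compared as the mean difference over the 4 treatments. Tetramer-positive cells had higher Plk4, the kinase of centriole duplication (1.85-fold, log2 difference 0.89 ± 0.20, adjusted p = 0.0382), Orc6, a subunit of the replication origin complex (1.69-fold, 0.76 ± 0.18), the metallothionein Mt2 (2.39-fold, 1.26 ± 0.30), Nrn1 (2.64-fold, 1.40 ± 0.31) and Chst2 (0.84 ± 0.20), with n = 11 libraries per gate. Cdkl2 passed as well (adjusted p = 0.0353), but it was listed at 0 in both tetramer-negative combination libraries and has no fold. Each was higher in all 4 treatments. Over the alternative settings the first 5 passed in 12, 9, 10, 11 and 6 of 31, and Cdkl2 in 10 of 30. G2 and mitosis was higher as a list (median log2 difference 0.53, 58 of 62 members higher, adjusted p = 1.04e-15, and adjusted p = 0.141 with an estimated correlation, range -0.49 to 0.86), as was S phase (median log2 difference 0.48, 45 of 47 members higher, adjusted p = 6.79e-13, and adjusted p = 0.0838 with an estimated correlation, range -0.071 to 0.59), with 12 members of each passing adjusted over the list alone and 2 and 0 over all genes. Genes of amino acid transport and ATF4 targets were at 0.27 (adjusted p = 0.00458, or 0.0896 with an estimated correlation, range 0.12 to 0.29), with the asparagine synthetase Asns at 1.08.

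Genes of naive and memory T cells were lower in tetramer-positive cells (median log2 difference -0.35, 23 of 30 members lower, adjusted p = 4.14e-06, and adjusted p = 0.0896 with an estimated correlation, range -0.41 to 0.24), with the survival gene Bcl2 at -1.09 ± 0.23 (adjusted p = 0.0281) and Pik3ip1 at -0.99 ± 0.24 (adjusted p = 0.0473). Of the 30 panel genes 0 passed over all genes. All 38 type I interferon genes were lower (median log2 difference -0.59, 38 of 38 members lower, adjusted p = 1.04e-15, and adjusted p = 0.0571 with an estimated correlation, range -0.71 to 0.14), with Xaf1 at -0.87 ± 0.18 and Ifi44 at -2.08 ± 0.49, and 12 passed adjusted over the list alone against 2 over all genes. The interferon gamma list was at -0.29 (adjusted p = 7.13e-11, or 0.0571 with an estimated correlation, range -0.40 to 0.0248), with the GTPase Igtp at -0.75. The cytokine receptor and JAK-STAT list stood at -0.22 (adjusted p = 1.30e-04, or 0.0896 with an estimated correlation, range -0.32 to 0.21), with the feedback inhibitor Socs2 at -1.38. CD8 T cell identity genes stood at -0.11 (adjusted p = 0.0493, or 0.477 with an estimated correlation, range -0.16 to -0.0275). Dendritic cell markers moved with these lists: all 15 were lower in tetramer-positive cells (median log2 difference -2.52, 15 of 15 members lower, adjusted p = 5.23e-14, and adjusted p = 0.0571 with an estimated correlation, range -3.40 to 0.0369), 4 over all genes and 10 adjusted over the list alone. Of the 10 genes with the largest falls, Clec10a is a dendritic marker of that list (-3.68), Klra6 belongs to the Ly49 receptors of natural killer cells (-3.37) and Zbtb16 is a transcription factor of innate-like T cells (-3.55), beside Kmo (-4.16) and Rnase6 (-3.02). The other 5 have no fold, since the dendritic markers Flt3 and Clec9a, Tbc1d9, Pirb and Pkib were listed at 0 in every library of 1 tetramer-positive group, Clec9a with the combination and the others with aCTLA4. These 10 were listed at 0 in 1 to 7 of the 11 tetramer-positive libraries, and passed in 7 to 20 of 30 alternative settings. Macrophage markers were at -0.75 (adjusted p = 6.2e-09, or 0.157 with an estimated correlation, range -1.40 to -0.15). Gamma delta T cell markers stood at -2.08 (adjusted p = 3.93e-06, or 0.0838 with an estimated correlation, range -2.88 to 0.48). Natural killer cell markers stood at -0.21 (adjusted p = 0.00573, or 0.0855 with an estimated correlation, range -1.05 to -0.0376). That median was -0.35 and -0.0999 without combination tetramer-positive replicates 1 and 2, -0.33 without combination tetramer-negative replicate 2 and -0.13 without control antibody tetramer-negative replicate 3.

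In all, 64 genes passed by limma between the gates, 7 higher and 57 lower, and 12 of 29 lists, of which 0 held with an estimated correlation and 9 by fry. Within single treatments fewer genes passed. By limma 0 genes passed with the control antibody, aPD1 or aCTLA4 (331, 274 and 718 at an unadjusted p under 0.05), and 30 with the combination, 15 higher and 15 lower, of which 13 are among the 64. That even split depended on the setting. Higher and lower genes numbered 2 and 12 with a pseudocount, 4 and 8 under the stricter filter and 0 and 3 in a fit of the 2 groups alone. They were 14 and 35 without the 3 libraries named above, 23 and 21 without a filter and 18 and 6 without a trend. The 30 were 231 and 46 without combination tetramer-negative replicates 1 and 2, where 1 library stands for the group, 17, 20 and 10 without tetramer-positive replicates 1, 2 and 3, 1 with library weights, 3 in a fit of the 2 groups alone, 12 under the stricter filter, 14 with a pseudocount and 0 with marker levels as covariates. With aCTLA4 3 genes passed without its tetramer-positive replicate 3, 5 with library weights and 8 in a fit of the 2 groups alone, with the control antibody 2 passed without its tetramer-negative replicate 3, and with aPD1 10 passed without a filter. Without the 3 libraries named above the counts were 1, 10, 25 and 49 for the control antibody, aPD1, aCTLA4 and the combination. The count of 64 was 0 without aCTLA4 tetramer-negative replicate 3, aPD1 tetramer-negative replicate 2, aPD1 tetramer-positive replicate 2, or control antibody tetramer-negative replicate 1 or 2, and 142 without aPD1 tetramer-positive replicate 1, 140 without control antibody tetramer-negative replicate 3 and 105 without combination tetramer-negative replicate 1. It was 10 without combination tetramer-negative replicate 2, 16 without aPD1 tetramer-negative replicate 3, 17 and 30 without control antibody tetramer-positive replicates 2 and 3, 25 and 37 without aCTLA4 tetramer-positive replicates 2 and 1, 28 and 40 without aCTLA4 tetramer-negative replicates 2 and 1, and 36 without combination tetramer-positive replicate 3. Dendritic markers differed within gates, at 6.39 in control antibody tetramer-positive replicate 1 against 4.44 and 4.31 in replicates 2 and 3, and at 4.54 in control antibody tetramer-negative replicate 3 against 7.19 and 7.14 in replicates 1 and 2. The count was 324 without these 2 libraries and aPD1 tetramer-positive replicate 1, chosen by dendritic markers, so this number is in part built in. It was 0 with marker levels as covariates, 2 without a trend and 6 without a filter, of which 0 were among the 64. It was 37 under the stricter filter, 41 with library weights and 1 with a replicate block.

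**Figure D2:**
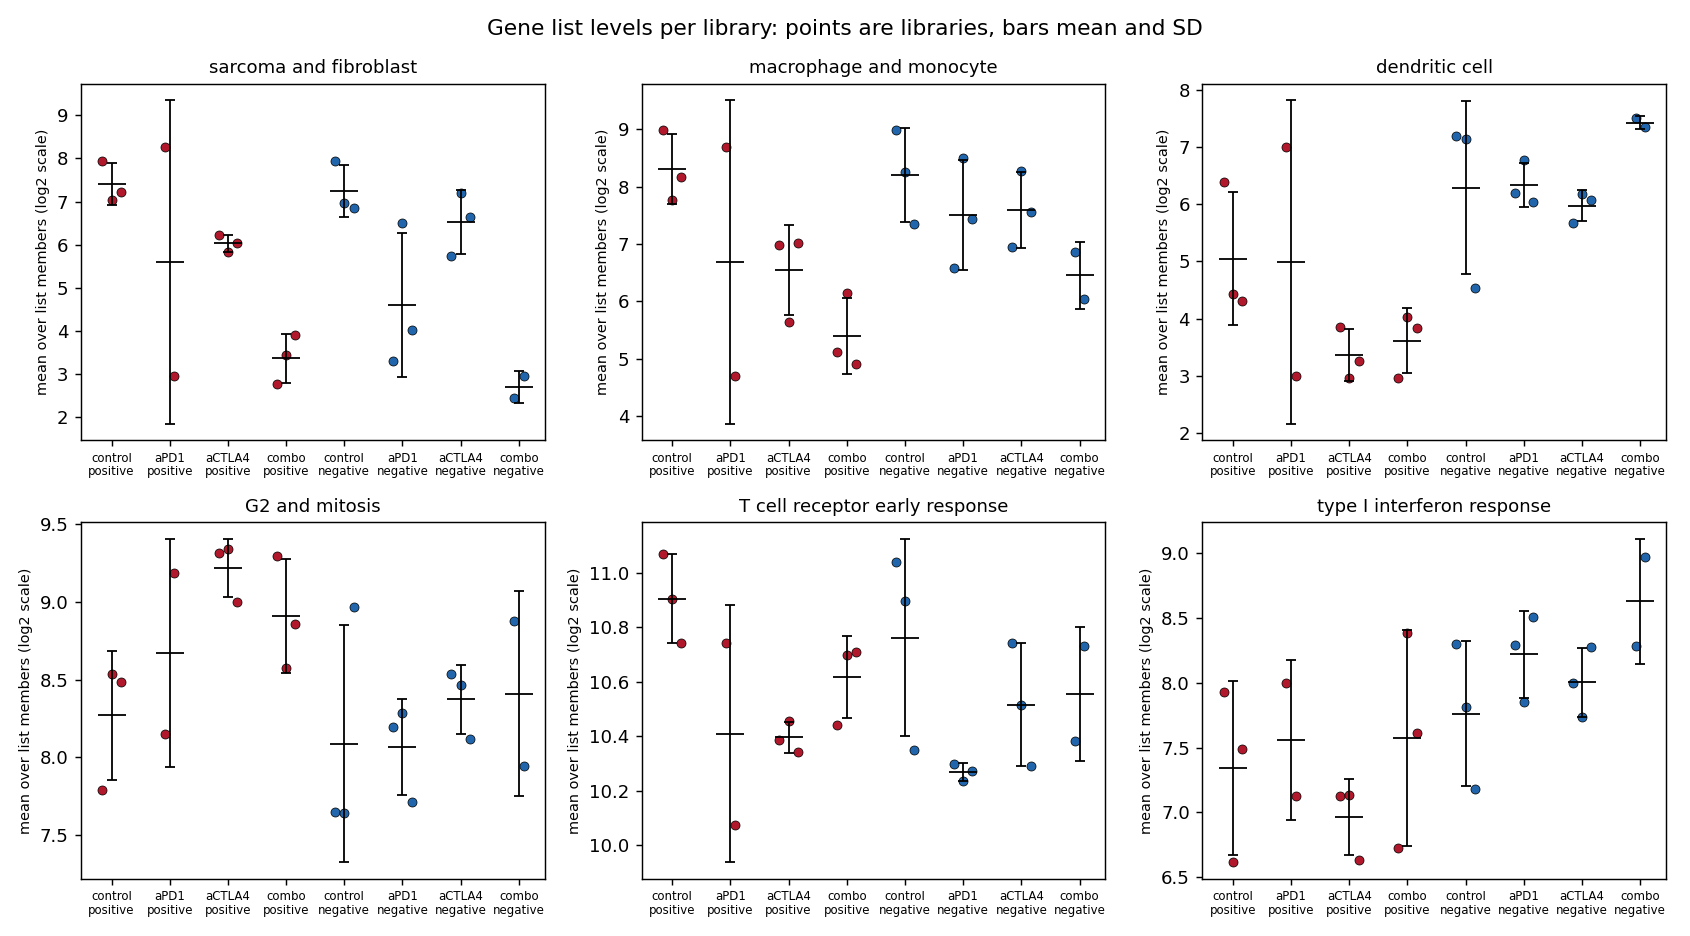
Mean log2 value over the members of 6 gene lists in each of the 22 libraries (y axis), by treatment and gate (x axis, red for tetramer-positive and blue for tetramer-negative), with bars for the mean and SD of each group. Sarcoma and fibroblast genes averaged 3.37 and 2.70 in the combination groups against 7.40 and 7.25 with the control antibody, and dendritic cell markers 3.61 in tetramer-positive against 7.43 in tetramer-negative cells of the combination.

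Whether the difference between the gates depended on treatment was tested with the 3 interaction terms together. 0 genes passed limma's F-test (397 at an unadjusted p under 0.05), and the smallest p belonged to Gpr146, Dgkg and Alg10b (adjusted p = 0.36, 0.557 and 0.557). The count was 51 without combination tetramer-negative replicate 1, 9 without its replicate 2 and 1 without aCTLA4 tetramer-positive replicate 1. It was 14 without a filter and 4 without a trend in the spread. Lists of fatty acid oxidation, cholesterol synthesis, endoplasmic reticulum stress, apoptosis, and CD4 and regulatory T cells passed in 0 of these comparisons.

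Marker levels per library were compared with exact two-sided permutation tests within gates or treatments, in a family of 44 tests. With the combination, sarcoma and fibroblast markers differed by -4.29 (log2 difference, exact p = 0.005, the smallest the permutations can give, adjusted p = 0.0733) and macrophage markers by -2.33 (exact p = 0.01, adjusted p = 0.088). With aCTLA4, red blood cell genes were higher by 3.63 (exact p = 0.005, adjusted p = 0.0733), B cell markers by 1.36 (exact p = 0.03), and sarcoma, macrophage and heat shock genes differed by -1.04, -1.18 and -0.41 (exact p = 0.02, 0.035 and 0.04). With aPD1, ribosomal protein genes differed by -0.25 (exact p = 0.015). Dendritic cell markers of tetramer-positive minus tetramer-negative cells differed by -2.25 (exact p = 0.00118, where the smallest possible is 2.5e-05, adjusted p = 0.0517), gamma delta T cell markers by -1.76 (exact p = 0.00725, adjusted p = 0.0798) and natural killer cell markers by -0.87 (exact p = 0.0173, adjusted p = 0.109). None passed after Benjamini-Hochberg adjustment over the 44 tests. With the median over members in place of the mean, the dendritic difference of -2.13 passed.

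**Figure D3:**
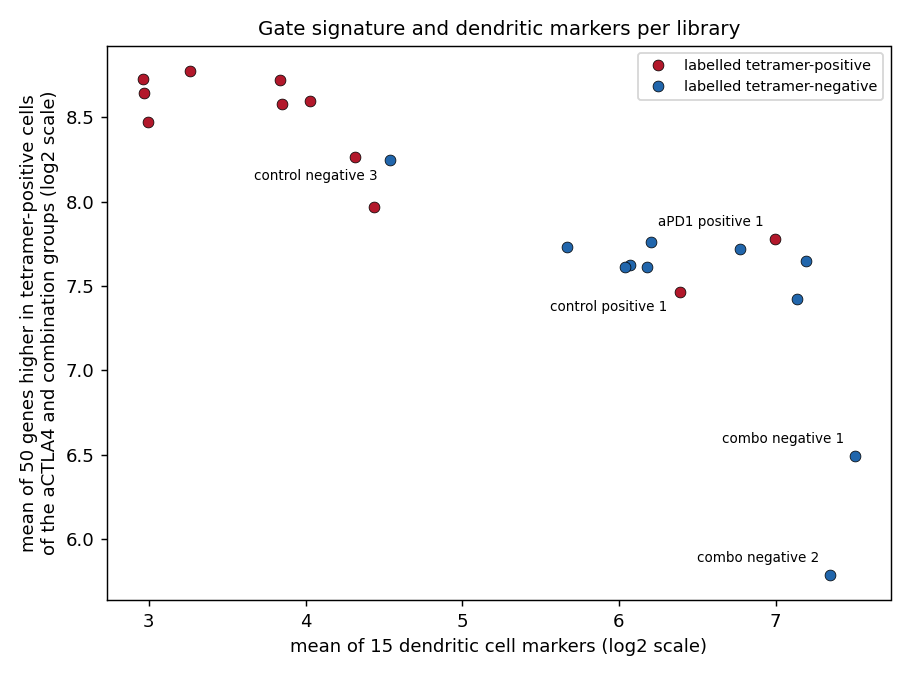
Mean log2 value of 50 genes that were higher in tetramer-positive cells of the aCTLA4 and combination groups (y axis) against the mean of 15 dendritic cell markers (x axis) in each of the 22 libraries, with red points for tetramer-positive and blue points for tetramer-negative labels. The aCTLA4 and combination libraries part on the y axis by construction, and control antibody tetramer-positive replicate 1 lies at 7.47 and control antibody tetramer-negative replicate 3 at 8.25.

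Responses to the 3 treatments in tetramer-positive cells were compared as correlations of log2 differences across 10000 genes, which are not independent replicates. All 3 comparisons use the same control libraries, which alone give a correlation. Between aCTLA4 and the combination r was 0.569 against a mean of 0.498 in 100 simulations of unchanged groups, with a covariance 0.216 above the simulated one. For aPD1 and the combination r was 0.506 against 0.448 (covariance 0.109 above), and for aPD1 and aCTLA4 0.495 against 0.448 (0.0493 above). Shared calls could not arise, since each pair holds a treatment without calls. The 3 control libraries are too few to split, so the excess cannot tell a shared response from genes that move together in them. Without 1 library r ranged from 0.497 to 0.675, 0.187 to 0.637 and 0.203 to 0.640 in that order.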

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

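The tests of marker shares and of the gate signature were chosen only after seeing the results; the depth tests and the splits were written before their values, those of the gates within treatments later than the others. Several gene lists passed limma's camera on the interaction of gate and treatment, which brought them here. None held with an estimated correlation. The values are the median log2 effect in tetramer-positive minus that in tetramer-negative cells.

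For aPD1 the difference was 0.36 (adjusted p = 0.0143) for S phase and 0.37 (adjusted p = 0.00863) for G2 and mitosis. Macrophage genes stood at -0.82 (adjusted p = 0.00863) and B cell genes at -3.13 (adjusted p = 0.0435). Natural killer cell genes stood at -0.50 (adjusted p = 0.0435) and red blood cell genes at -3.68 (adjusted p = 0.0019). With an estimated correlation adjusted p was 0.552 for B cell and natural killer cell genes and 0.747 for the others. For aCTLA4 the difference was 0.31 (adjusted p = 0.00196) for S phase and 0.50 (adjusted p = 4.42e-06) for G2 and mitosis. Early response genes stood at -0.25 (adjusted p = 0.0433) and type I interferon genes at -0.36 (adjusted p = 0.0132). Interferon gamma genes stood at -0.25 (adjusted p = 0.0346) and macrophage genes at -1.01 (adjusted p = 0.00133). Dendritic cell genes stood at -1.33 (adjusted p = 0.0281) and natural killer cell genes at -1.56 (adjusted p = 9.29e-04). With an estimated correlation adjusted p was 0.102 for natural killer cell genes and 0.517 for the others. The combination gave -0.38 (adjusted p = 0.0161) for naive and memory and -0.42 (adjusted p = 0.0224) for type I interferon genes. Macrophage genes stood at -1.34 (adjusted p = 0.00123) and dendritic cell genes at -2.78 (adjusted p = 0.00123). With an estimated correlation adjusted p was 0.56, 0.765, 0.688 and 0.363 in that order. Each value subtracts the gate difference with the control antibody. That difference includes control antibody tetramer-positive replicate 1 and tetramer-negative replicate 3, which narrow it for dendritic cell genes. The aPD1 values also hold aPD1 tetramer-positive replicate 1. These lists were not tested without these libraries.

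The first pattern weighed was the fall of sarcoma and fibroblast genes with the combination. Of all members detected with the control antibody, a share of 0.941 was lower with the combination in tetramer-negative cells and 0.971 in tetramer-positive cells, which is consistent with fewer tumour and stromal cells or less of their free RNA in the sorted samples. The described enrichment for CD45 and sort for CD3 and CD8 would remove such cells and counts against this source, apart from free RNA, doublets or incomplete sorting, none of which was measured. The share lies close to the pattern itself and does not tell cells from free RNA. Lower depth did not account for it: 0 of 10000 lists matched for level had a median as low (-4.65 against a lowest of -1.60). A biological cause within T cells was not tested.

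The second was the higher dendritic cell genes in tetramer-negative cells. A share of 1 of the 17 members detected there was higher in tetramer-negative cells, which is consistent with dendritic cells, or doublets with them, passing that gate, though this share too lies close to the pattern itself. The described sort for live CD3 and CD8 positive cells would remove single dendritic cells and counts against them as a source. Tetramer-positive libraries were not uniformly shallower, as the deepest library was tetramer-positive and the shallowest tetramer-negative. The depth test thus had little to exclude. In it 0 of 10000 matched lists had a median as low (-2.52 against a lowest of -1.31). The lower type I interferon genes of tetramer-positive cells could come from the same cells, because with the marker covariates their median was 0.14, but those covariates turned 8 of 12 lists between the gates, so this does not separate causes.

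The third was that 3 libraries lay on the side of the other gate. Over 50 genes that part the gates in other treatments, control antibody tetramer-positive replicate 1 minus tetramer-negative replicate 3 was -0.78, against the sign the labels imply. This is 1.86 SD of a difference between 2 libraries of one group with the SD of all groups, which the doubted libraries widen, and 3.01 SD with the SD of the 5 other groups, 4 of which served to choose the genes. The 2 libraries were picked because they lay on the wrong side. So this test does not decide, other cell types as the only difference and an exchange of these 2 libraries cannot be told apart by it, and 6 of the 50 are cell cycle genes. An exchange may explain it but stays a hypothesis, nothing was regrouped, and aPD1 tetramer-positive replicate 1 has no such partner.

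Counts were also set against other splits of the same libraries. Between the gates 1 of 100 splits, the real one, gave as many as 64 genes (highest other 25). Random grouping was thus unlikely for the gene count. For lists it was not, as 21 of 100 gave as many as 12 (highest other 17). With 10 splits no share under 0.05 can arise. There, splits with as many genes numbered 10 for aCTLA4 in tetramer-positive cells (0 genes, highest other 1), 1 for the combination (6, highest other 2), 10 for aPD1 and 10 for aCTLA4 in tetramer-negative cells (0 each, highest other 1 and 3) and 10 for the combination against aCTLA4 (0, highest other 3). Between the gates they numbered 10 with the control antibody (0, highest other 17) and 10 with aCTLA4 (0, highest other 0). The split with 17 genes exchanges control antibody tetramer-positive replicate 1 and tetramer-negative replicate 3 and points to a structure of these samples, which either explanation above would bring. For lists they numbered 1 for aCTLA4 in tetramer-positive cells (13, highest other 10), 3 for the combination (11, highest other 13), and 4 each for aPD1 and aCTLA4 in tetramer-negative cells (8 and 7, highest other 12 and 12).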

How the results depend on the processing

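Covariates, libraries to leave out by dendritic markers, and lists in direct comparisons were chosen only after seeing the results. With 2 or 3 libraries per group, few genes passed and every gene count moved by over 1.5 times in at least 1 setting. The trimmed mean shift kept all 103 list results and 364 of 366 gene results. With a pseudocount 102 of 103 lists and 348 of 366 genes kept both direction and call, with weights 100 and 349, without a trend 98 and 323, and without a filter 95 and 323. Most of these gene results did not pass in the main fit, so for them a kept call means no call. Of those that did pass, 11, 17, 42 and 43 lost the call in the same order. Without a trend or a filter that was most of the passing genes. No setting moved the median of all genes by over 0.1. The shallower combination libraries limit calls of low genes at 0. Groups of 2 or 3 cannot settle whether replicate numbers pair the samples. Between the gates r was -0.174 to 0.0863 (10 pairs, 0 over 0.1). Between treatment and control of one gate it was -0.0459 to 0.197 (16 pairs, 3 over 0.1, among them both aPD1 tetramer-positive pairs). With a replicate block the counts were 4 and 17 for the combination in tetramer-positive and tetramer-negative cells, 9 for it against aPD1 and 1 between the gates. Except where said, the cause was not tested.

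Without a filter the counts were 4 genes for aPD1 in tetramer-positive and 2 in tetramer-negative cells, 7 for aPD1 against aCTLA4, 10 and 5 for the combination against aPD1 and aCTLA4, 6 between the gates and 14 for the interaction; more low genes are tested there. Under the stricter filter, with fewer genes tested, they were 3 and 2 for the combination in tetramer-positive and tetramer-negative cells and 37 between the gates, the lists numbered 7 and 6 for the combination and 5 for aPD1 in tetramer-negative cells, and the macrophage median for the combination in tetramer-negative cells was 0.24. With a pseudocount the combination gave 13 and 0. Without a trend the counts were 1 for the combination in tetramer-positive cells, 1 and 1 for aPD1 and aCTLA4 in tetramer-negative cells, 0 for the combination against aPD1, 2 between the gates and 4 for the interaction. With weights they were 0 for the combination in tetramer-negative cells and 41 between the gates. With only the groups compared they were 4 and 5 for aCTLA4 in tetramer-positive and tetramer-negative cells, 11 and 0 for the combination, and 0 for the combination against aPD1. With an estimated correlation 0 lists passed in each of 7 comparisons, and by fry 0, 0 and 1 in tetramer-positive and 0, 0 and 1 in tetramer-negative cells for aPD1, aCTLA4 and the combination. With the median over members the dendritic level differed by -2.13 between the gates.

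Without the 3 libraries chosen by their dendritic markers, the counts were 1 for the combination in tetramer-positive cells, 3 and 5 for aPD1 and aCTLA4 in tetramer-negative cells, 0 for the combination against aPD1 and 324 between the gates, which is partly built in by that choice. For the combination in tetramer-negative cells the values that turned were Siglech -0.0233 and dendritic cell -0.0233. For aPD1 against aCTLA4 the values that turned were G2 and mitosis 0.0178 and dendritic cell -0.0189. For the combination against aPD1 the values that turned were G2 and mitosis -0.30, macrophage and monocyte 0.50, dendritic cell 0.0859, sarcoma and fibroblast 0.65 and red blood cell -0.27.

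With the sarcoma and dendritic levels as covariates, which are built from tested lists and nearly follow gate and treatment, 44 of 103 lists kept direction and call, 30 kept direction but lost the call and 29 turned, and of 366 genes 278, 39 and 49. The gene counts were 0 for the combination in either gate, for the combination against aPD1 and between the gates, and the lists numbered 7 for aCTLA4 in tetramer-positive cells, 5 for aPD1 and 7 for the combination in tetramer-negative cells and 3 between the gates. Those that turned for aPD1 in tetramer-positive cells were sarcoma and fibroblast 0.0967. For aCTLA4 in tetramer-positive cells the log2 values that turned were Siglech 0.40 and sarcoma and fibroblast 1.57e-04. Those that turned for the combination in tetramer-positive cells were Incenp -0.0767, Arg1 0.77, Siglech 0.28, Tmem176a 0.12, Sparc 0.83, Hba-a2 -2.58, Alas2 -3.10, Hbb-bt -4.16, Hba-a1 -3.46, heat shock and dissociation stress 0.18, dendritic cell 0.27, sarcoma and fibroblast 0.31 and red blood cell -3.67. For aPD1 in tetramer-negative cells the log2 values that turned were Atf4 0.0254, Cd79b -3.70, Pou2af1 -1.03, Col3a1 0.91, Hbb-bs -0.91, Hbb-bt -1.53, Hba-a2 -1.08, B cell and plasma cell -0.75, sarcoma and fibroblast 0.0388 and red blood cell -1.30. Those that turned for the combination in tetramer-negative cells were Ifit1 -0.41, Trim30a -0.15, C1qc 0.72, Ccl2 1.36, C1qa 0.72, H2-DMb2 -0.27, Col1a2 1.72, Hbb-bs -4.68, Hbb-bt -5.97, Alas2 -1.69, Hba-a2 -5.69, interferon gamma response and antigen presentation -0.41, sarcoma and fibroblast 0.00445 and red blood cell -5.73. For aPD1 against aCTLA4 the log2 values that turned were S phase and DNA replication 0.0221, G2 and mitosis 0.23 and dendritic cell -0.33. Those that turned for the combination against aPD1 were G2 and mitosis -0.0904, dendritic cell 0.21, sarcoma and fibroblast 0.22 and red blood cell -0.12. For the combination against aCTLA4 the log2 values that turned were G2 and mitosis 0.17 and sarcoma and fibroblast 0.18. Those that turned for the gates were Flt3 0.91, Lig1 -0.11, Bub1b -0.13, Top2a -0.42, Bcl2 0.20, Pik3ip1 0.17, Ly6c2 0.15, Socs2 0.25, Socs1 0.29, Pim2 0.26, Isg20 0.48, Asns -0.31, Cd3d 0.00666, Cd8a 0.0892, H2-Ab1 0.53, H2-Aa 0.86, Siglech 0.13, Klra1 2.40, Fcer1g 1.44, Tmem176a 1.13, a gene model of the gamma delta list 0.999, S phase and DNA replication -0.071, G2 and mitosis -0.49, naive and memory T cell 0.24, cytokine receptors and JAK-STAT 0.21, type I interferon response 0.14, interferon gamma response and antigen presentation 0.0248, dendritic cell 0.0369 and gamma delta T cell 0.48. Between the gates 0 of 12 lists kept both direction and call.

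Without 1 library, gene counts ranged from 0 to 9, 0 to 1 and 0 to 9 for aPD1, aCTLA4 and the combination in tetramer-positive cells, from 0 to 2, 0 to 2 and 0 to 200 in tetramer-negative cells, from 0 to 1 for aPD1 against aCTLA4, from 1 to 3 and 0 to 3 for the combination against aPD1 and aCTLA4, from 0 to 142 between the gates and from 0 to 51 for the interaction. Lists ranged from 10 to 17, 8 to 14 and 9 to 14, from 6 to 11, 5 to 10 and 5 to 10, and from 11 to 14 in the same order of treatments and gates. Levels ranged from -0.50 to -0.31 (heat shock), -1.39 to -0.96 (macrophage), 1.09 to 1.54 (B cell), -1.21 to -0.85 (sarcoma) and 3.29 to 4.03 (red blood cell) with aCTLA4, from -0.29 to -0.21 (ribosomal) with aPD1, from -2.54 to -2.12 (macrophage) and -4.42 to -4.12 (sarcoma) with the combination, and from -2.75 to -1.75 (dendritic), -1.07 to -0.66 (natural killer) and -2.29 to -1.22 (gamma delta) between the gates. The correlations of responses ranged from 0.203 to 0.640, from 0.187 to 0.637 and from 0.497 to 0.675 (aPD1 with aCTLA4, aPD1 with the combination, aCTLA4 with the combination). Without 1 library, values that turned for aCTLA4 in tetramer-negative cells ranged as follows: oxidative phosphorylation -0.35 to 0.0484. For aPD1 against aCTLA4: G2 and mitosis -1.00018 to 0.0178 and dendritic cell -0.0189 to 3.19. For the combination against aPD1: G2 and mitosis -0.30 to 0.66, macrophage and monocyte -2.57 to 0.50, dendritic cell -3.87 to 0.0859, sarcoma and fibroblast -5.44 to 0.65 and red blood cell -0.27 to 4.89. For aPD1 in tetramer-positive cells: Arg1 -8.89 (against 1 library at 0) to 0.35, Sparc -7.52 to 0.77, Dcn -6.06 to 0.79, Col4a1 -7.19 (against 1 library at 0) to 0.036, Col1a1 -5.71 to 0.50, S phase and DNA replication -0.0938 to 0.60, G2 and mitosis -0.15 to 0.90, macrophage and monocyte -2.79 to 0.48 and sarcoma and fibroblast -4.82 to 0.77. For the combination in tetramer-negative cells: Hba-a2 -1.27 to 5.95, red blood cell -0.42 to 5.96, macrophage and monocyte -0.96 to 0.13, Siglech -0.0233 to 2.08 and dendritic cell -0.0233 to 1.69. For the combination in tetramer-positive cells: Tmem176a -1.86 to 0.0081. For the combination against aCTLA4: cytotoxic effector -0.0752 to 0.44.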
